A study of Mus musculus with 4 samples.

How the data were processed

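Leukocytes were sequenced from mouse left lungs transplanted between mice of the same B6 strain. The lungs had been stored for 60 min at 4 °C and for a further 45 min at 28 °C, and were collected 2 h after reperfusion. Recipients received resolvin D1 (RvD1, a lipid mediator made from docosahexaenoic acid) intravenously before transplantation, at 200 ng per mouse in 200 µL of 1% ethanol, or vehicle, per the labels' protocols. Cells were sorted on the pan-leukocyte marker CD45 and separated into donor-derived and recipient-derived cells, per the labels. This gives 4 groups (vehicle donor, RvD1 donor, vehicle recipient, RvD1 recipient) of 1 library each, and 2 lungs were pooled in each library, per the labels' protocols. Whether the donor and recipient libraries of a treatment came from the same lungs is not given in the sources used here.

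The libraries were made with the 10x Genomics 3' v3 kit and sequenced on a NovaSeq instrument, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode for 32285 genes, made with Cell Ranger, per the file headers. The headers give Cell Ranger 7.0.1 for both RvD1 libraries and Cell Ranger 6.1.1 for both vehicle libraries. The software version and the treatment therefore cannot be told apart in any comparison of RvD1 with vehicle, and whether reads in introns were counted is not given in the sources used here. Each comparison of recipient with donor cells lies within 1 version. The genome build was mm10, and Seurat 4.0.0 was used in the study, per the submitters' processing notes. No cell type annotation was used from the authors, and doublet removal before deposit is not stated.

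Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet, as implemented in scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells, and removed. All 4 libraries were clustered together without batch integration, because integration of groups of 1 library each can remove the treatment. Counts were log-normalised and 2000 variable genes were chosen per library and combined, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) were used. Clusters were named from 22 marker sets. A cluster was named when at least 3 markers of the class were each detected in at least 10% of its cells. It stayed unnamed when a second lineage reached 70% of the best score, when more of its 10 leading genes were markers of another class than of its own, or when its median UMI count was low for its libraries and no marker of its own was among the leading genes. The details of this naming rule were settled after the clusters had been seen, and the 70% was lowered then. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and anndata 0.12.19, and figures were drawn with matplotlib 3.10.9.

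UMIs were summed per class and library and scaled to CPM by the class's own total. A class was compared when both libraries held at least 100 of its cells, and a gene was described when it had at least 100 UMIs over the 2 libraries. Ratios are on the log2 scale with no pseudocount, and a library at 0 was set to a floor of 3 counts. The 95% intervals of ratios come from exact binomial intervals, those of CPM values from exact Poisson intervals and those of shares from exact Clopper-Pearson intervals. All intervals and floors cover counting error only. With 1 library per group there is no replicate check, so no test between conditions was run and no p-value is given. A ratio compares the libraries named and not the conditions.

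For each of 21 gene lists, the median log2 ratio over members with enough UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries. The genes described by name are the 10 higher and 10 lower genes per class with the largest smaller absolute log2 ratio of both contrasts, given at least 1.5-fold in the same direction in both. Up to 4 members of each list with the largest mean absolute log2 ratio and the resolvin receptor genes were added. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and antigen receptor segment genes and unnamed models were left out of the ranking. Counts of genes use 2-fold in both contrasts. The comparisons, marker sets, lists, filters, the rule for genes described by name and most alternatives were fixed before the data were examined; the rule for naming clusters was not. A gene symbol shared by more than 1 gene identifier (38 symbols) is counted per identifier. Gene positions are from GENCODE release M21 on GRCm38 (mm10).

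The calculation of ratios was tested on simulated counts with known changes. A gene counted as recovered when it was at least 1.5-fold in the right direction in both origins, a looser cut-off than the 2-fold used for counts of genes. The simulated counts varied by counting error only. High recovery was therefore built in and does not speak to variation between libraries, lungs or cell mixes. For RvD1 against vehicle in both origins, the simulation ran on 6568 genes in neutrophils, and 100.0% of the genes changed 2-fold, 3-fold and 4-fold were each recovered in the right direction. In classical monocytes it ran on 5419 genes, with 98.39% recovered at 2-fold and 100.0% at both 3-fold and 4-fold. In nonclassical monocytes it ran on 6216 genes, with 100.0% recovered at 2-fold, 3-fold and 4-fold. A simulated list with no shift was also placed among random lists: in classical monocytes, RvD1 over vehicle in donor cells (8686 genes), it lay at percentile 2.03, so a low percentile of a single list in 1 contrast can arise by chance.

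The alternatives were a minimum of 500 genes per cell, at most 5% mitochondrial UMIs, no doublet removal, Leiden resolutions of 0.5 and 2, clustering of each library alone, scaling by the median ratio over genes, a total without mitochondrial, ribosomal and haemoglobin genes, equal weight for every cell, minimums of 50 and 200 UMIs per gene, and thinning of every cell to 500 UMIs. Further alternatives, chosen after seeing the data, subtracted the median ratio of genes of like intron length in 20 bins, left out cluster 0 of the neutrophils, or left out cluster 15 of the nonclassical monocytes with a minimum of 90 cells.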

Results

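The 4 libraries held 5743 (vehicle donor), 5195 (RvD1 donor), 5987 (vehicle recipient) and 7836 (RvD1 recipient) barcodes with 61294707, 44338340, 42199775 and 49967935 UMIs. The filters removed 85, 103, 69 and 213 barcodes in the same order, and 131, 68, 89 and 278 cells were called doublets and removed. The analysis used 5527, 5024, 5829 and 7345 cells. The median UMI count per cell was 7905 in vehicle donor, 6463.5 in RvD1 donor, 5830 in vehicle recipient and 5386 in RvD1 recipient cells, and the median number of genes was 2493, 1945.5, 1626 and 1641. After every cell was thinned to 500 UMIs (0 cells were shallower), the medians were 351, 332, 319 and 318 genes. The median ribosomal share of UMIs per cell was 3.13% in the vehicle recipient library and between 12.1% and 13.7% in the others. Within neutrophils the ribosomal share of UMIs was 2.15% in vehicle recipient and 2.37% in RvD1 recipient cells.

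The first question was which leukocytes of the graft came with the donor lung and which entered from the recipient. Neutrophils, the first responders to reperfusion, made up 57.3% (95% interval 56.0 to 58.6) of vehicle recipient and 41.3% (40.2 to 42.5) of RvD1 recipient cells. Of donor cells they made up 25.7% (24.6 to 26.9) with vehicle and 37.8% (36.5 to 39.2) with RvD1. Lung-resident classes were almost confined to the donor libraries: alveolar macrophages numbered 218 and 42 among vehicle and RvD1 donor cells and 4 and 6 among recipient cells. Their median depth was 28779.5 UMIs and 4968.5 genes in vehicle donor but 3181 UMIs and 1060 genes in RvD1 donor cells. Whether the RvD1 donor cells of this class were intact was not tested. Group 2 innate lymphoid cells numbered 74 and 87 in the donor libraries and 1 in the vehicle recipient library. In the RvD1 recipient library 0 of 7345 cells were found, which allows a share of up to 0.0408% at the floor of 3 counts and of 0.0502% at the exact upper limit. Dendritic cells (DCs) made up 5.66% and 3.80% of donor cells and 0.275% and 0.613% of recipient cells.

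Classical monocytes, which carry Ly6c2 and Ccr2 and are recruited from blood, made up 9.84% (9.07 to 10.7) of vehicle donor, 14.5% (13.5 to 15.5) of RvD1 donor, 2.87% (2.45 to 3.33) of vehicle recipient and 3.29% (2.90 to 3.73) of RvD1 recipient cells. Nonclassical monocytes, which patrol the vessel wall, made up 9.88% (9.10 to 10.7), 5.67% (5.05 to 6.35), 3.33% (2.88 to 3.82) and 4.96% (4.47 to 5.48) in the same order. T cells made up 15.1% (14.1 to 16.0), 13.6% (12.7 to 14.6), 13.5% (12.6 to 14.4) and 25.2% (24.2 to 26.2). B cells made up 8.16%, 5.47%, 15.05% and 12.9%, and NK cells 14.1%, 8.32%, 6.09% and 7.52%. These are shares of sorted CD45-positive cells and not of all lung cells, and the sort, the digestion and the gap in UMIs per cell between libraries can set them. Shares of a library also depend on each other, so a change in 1 class moves the others. Unnamed clusters (18, 20, 24 and 27) held 3.29%, 5.06%, 0.480% and 1.81% of cells. With each library clustered alone, the RvD1 minus vehicle difference in T cells among recipient cells was 5.69 points in place of 11.7, that in classical monocytes among donor cells was 0.727 points in place of 4.67 and that in neutrophils among donor cells was 22.7 points in place of 12.1. With Leiden resolution 2 the neutrophil difference was -9.98 points in recipient cells in place of -16.0.

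**Figure D1:**
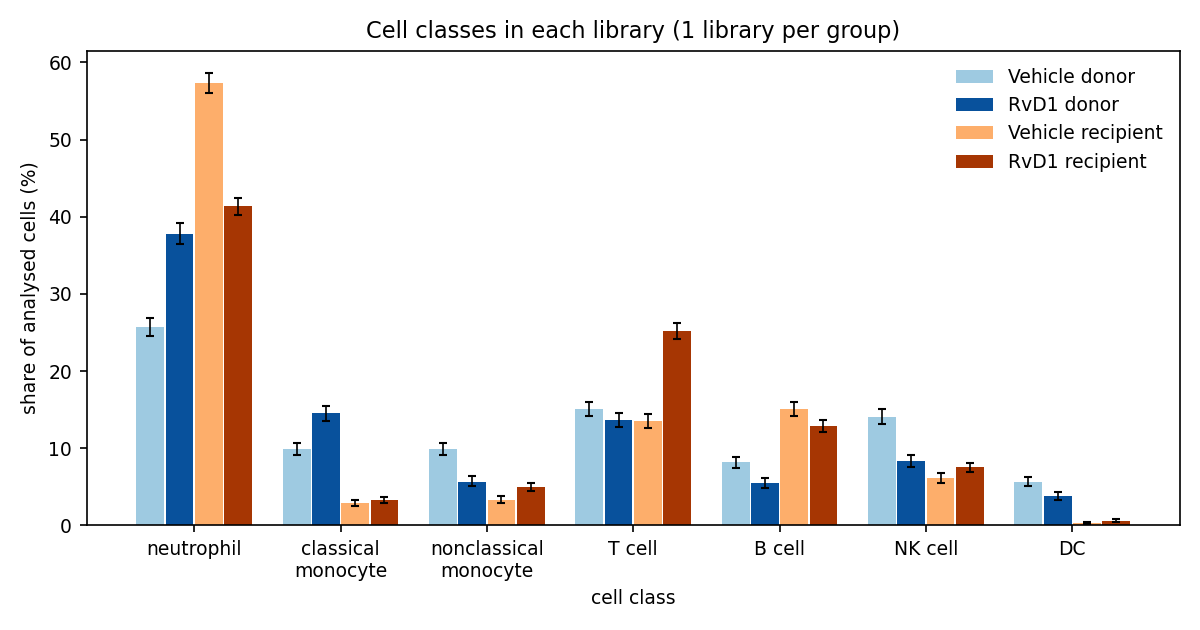
Share of analysed cells (percent, y axis) in each cell class (x axis) for the 4 libraries, with exact 95% binomial intervals that cover counting error only. Neutrophils reach 57.3% of vehicle recipient cells and 25.7% of vehicle donor cells.

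The second question was how RvD1 libraries differed from vehicle libraries within a class, first in donor and then in recipient cells. Both RvD1 libraries were counted with Cell Ranger 7.0.1 and both vehicle libraries with 6.1.1, so treatment and software version cannot be told apart in these ratios. In neutrophils, Wfdc17, a small secreted protein that restrains macrophage activation, was higher with RvD1 in both origins, with log2 ratios of 1.62 (1.58 to 1.67) in donor and 1.39 (1.34 to 1.44) in recipient cells. Its level was 703 CPM in vehicle donor and 2168 CPM in RvD1 donor neutrophils. Cxcr1, a chemokine receptor, was higher by 1.44 (0.95 to 1.97) and 1.16 (0.76 to 1.56), and Ddx28, a mitochondrial RNA helicase, by 2.28 (1.70 to 2.92) and 1.64 (1.18 to 2.12). Lower with RvD1 were Slc8a2, a sodium/calcium exchanger, at -3.67 (-4.26 to -3.13) and -4.30 (-4.97 to -3.70), Rmi2, a DNA repair gene, at -3.34 and -3.50, Qtrt1, which modifies transfer RNA, at -3.10 and -3.74, and Atg4c, an autophagy protease, at -2.96 and -2.79. Of 6569 genes described in both origins, 28 were at least 2-fold higher and 257 at least 2-fold lower with RvD1 in both. Across these genes the log2 ratios in donor and recipient cells had a Spearman correlation of 0.69; genes are not independent replicates.

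Hmox1 and Il10, which limit inflammation, were lower in RvD1 neutrophils, while the anti-inflammatory list as a whole lay within the random lists, at -0.13 (percentile 20.7) and -0.004 (32.5). Hmox1, which degrades haem, had log2 ratios of -1.24 (-1.35 to -1.13) in donor and -2.24 (-2.37 to -2.11) in recipient cells, and the cytokine gene Il10 had -1.17 (-1.51 to -0.84) and -1.49 (-1.84 to -1.15). These were the 2 of 14 measured anti-inflammatory genes at least 1.5-fold lower in both origins, and 0 were higher. S1pr1, the receptor for sphingosine-1-phosphate, was at -2.42 and -2.01, the survival gene Bcl2 at -1.16 and -1.24, and the adhesion gene Pecam1 at -1.73 and -1.08. In glycolysis, Pfkl (phosphofructokinase) was higher at 1.24 and 1.00 and the hexokinase gene Hk3 lower at -0.95 and -1.14. Fpr2, the best known RvD1 receptor gene, was at 0.03 (-0.05 to 0.12) and 0.08 (0.01 to 0.14), and its sign in recipient cells turned with other scalings. Cmklr1, the receptor gene for resolvin E1 and chemerin, was at -0.81 (-1.26 to -0.37) and -1.35 (-1.87 to -0.86).

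Different clusters held most neutrophils of each treatment, cluster 0 with vehicle and clusters 1, 3 and 7 with RvD1. Cluster 0 was led by genes that were lower with RvD1, such as Fnip2 and Pnpla7, so leaving it out selects cells on the result. Without cluster 0, 15 genes were at least 2-fold higher and 92 lower, and in donor cells Hmox1 was at -0.37, Il10 at -0.50 and Pecam1 at -0.90. When each library was clustered alone, 15 genes were higher and 159 lower, Pecam1 was at -0.38 and Cmklr1 at -0.21 in donor cells. The median log2 ratio of all described genes in recipient neutrophils was 0.12.

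Ddx28 (ENSMUSG00000045538) lies on chromosome 8 at 106009621 to 106011882, Wfdc17 (ENSMUSG00000069792) on chromosome 11 at 83703991 to 83706268 and Slc8a2 (ENSMUSG00000030376) on chromosome 7 at 16129826 to 16161063. Ccl3 (ENSMUSG00000000982) lies on chromosome 11 at 83647844 to 83649355, Gbp2 (ENSMUSG00000028270) on chromosome 3 at 142620602 to 142638008 and Il17a (ENSMUSG00000025929) on chromosome 1 at 20730905 to 20734496. These are whole gene bounds, and the assay counts the 3' ends of transcripts.

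**Figure D2:**
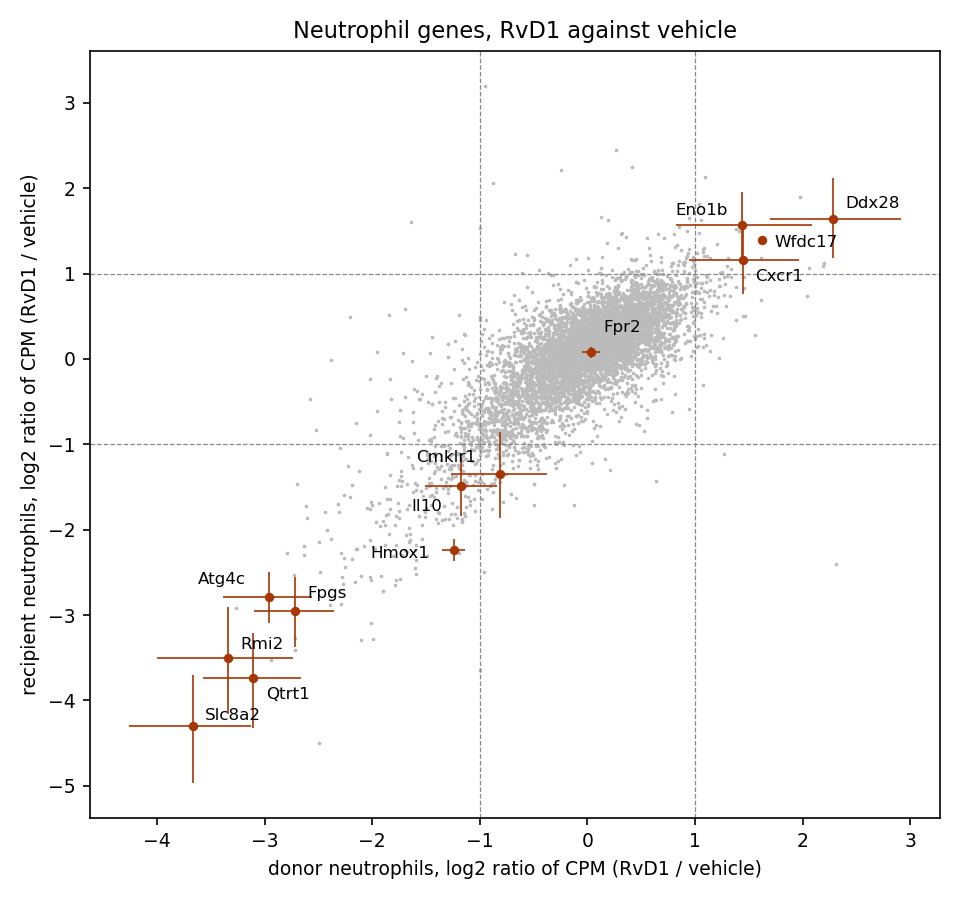
Log2 ratio of CPM, RvD1 over vehicle, in donor (x axis) and recipient (y axis) neutrophils; each grey point is 1 of 6569 genes with at least 100 UMIs in both contrasts, and labelled genes have 95% intervals for counting error. Dashed lines mark 2-fold, with Wfdc17 at 1.62 and 1.39 and Slc8a2 at -3.67 and -4.30.

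Interferon-stimulated genes, the antiviral programme induced by type I and type II interferons, were lower with RvD1 in neutrophils, both monocyte classes and T cells. In neutrophils the list's median log2 ratio was -0.73 in donor (percentile 0.0 among random lists) and -0.28 in recipient cells (percentile 0.03), with 7 of 25 measured members at least 1.5-fold lower in both origins and 1 higher. In classical monocytes the medians were -0.72 (percentile 0.0) and -0.32 (0.26), with 5 of 19 lower, and in nonclassical monocytes -0.80 (0.0) and -0.21 (0.67), with 6 of 18 lower. In T cells they were -0.82 (0.0) and -0.29 (0.13), with 3 of 20 lower. Gbp2, an interferon-induced guanylate-binding protein, was at -1.51 (-1.79 to -1.24) and -1.84 (-2.28 to -1.42) in classical monocytes, at -2.58 and -1.75 in nonclassical monocytes and at -1.46 and -0.67 in T cells. In T cells Ifit1, which binds foreign RNA, was at -1.40 and -0.82 and Slfn5 at -0.92 and -0.88. In B cells the medians were -0.14 (percentile 77.1) and 0.15 (97.3), and in NK cells -0.05 (71.2) and -0.10 (28.2).

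The interferon list depended on how neutrophils were defined. Its median in donor neutrophils was -0.03 with each library clustered alone and -1.50 without cluster 0, and in recipient neutrophils -0.83 without cluster 0. Without cluster 15 the median in donor nonclassical monocytes was -0.34.

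**Figure D3:**
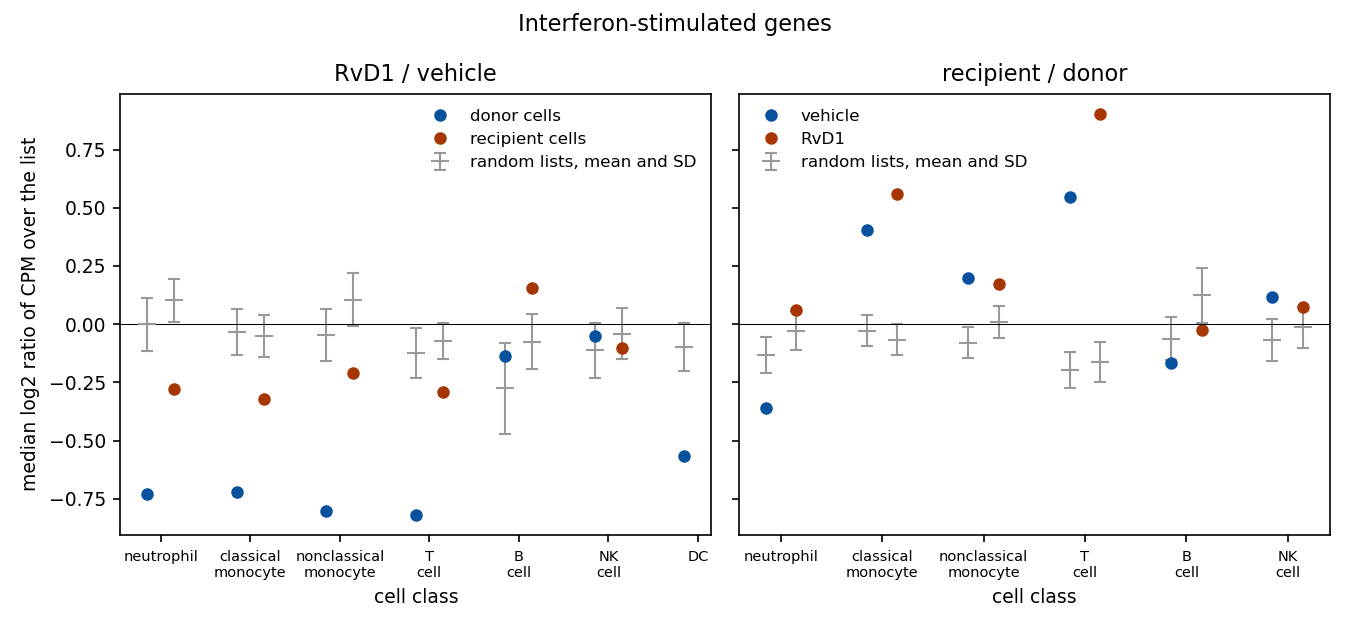
Median log2 ratio of CPM over the interferon-stimulated genes (y axis) per cell class (x axis), RvD1 over vehicle on the left and recipient over donor on the right; grey marks give the mean and SD of random lists matched on expression. Donor T cells are at -0.82 and donor classical monocytes at -0.72 on the left, and T cells are at 0.55 with vehicle and 0.90 with RvD1 on the right.

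In classical monocytes, P2rx7, Nlrc5, Thbd and Mt2 were among the genes lower with RvD1. P2rx7, the ATP receptor that activates the inflammasome, was at -1.36 (-1.70 to -1.02) and -2.15 (-2.83 to -1.51), Nlrc5, which drives MHC class I genes, at -1.62 and -1.26, Thbd (thrombomodulin) at -1.42 and -1.29 and the metallothionein gene Mt2 at -1.30 and -1.78. Tap1, the peptide transporter for MHC class I, was at -0.98 (-1.18 to -0.79) and -0.79 (-1.15 to -0.43). Of 19 antioxidant genes, 4 were at least 1.5-fold lower in both origins and 0 higher, among them Hmox1 at -1.10 and -1.59, the cystine transporter gene Slc7a11 at -0.70 and -0.92 and Gclc, which makes glutathione, at -0.86 and -0.60. That list's medians were -0.07 (percentile 19.96) and -0.40 (0.0), those of the TNF list -0.31 (0.05) and -0.15 (8.08) and those of the inflammasome list -0.20 (6.05) and -0.29 (1.74). Heat shock genes had medians of -0.62 (0.0) and -0.29 (0.67), with the chaperone gene Hsp90aa1 at -1.01 and -0.33. Higher were Tnfrsf11a, the receptor RANK, at 1.56 (1.31 to 1.81) and 1.67 (1.08 to 2.30) and Plxdc2, a plexin-domain protein, at 1.14 and 2.95. Eicosanoid and resolvin enzyme genes had medians of 0.28 (98.5) and 0.27 (99.8). Fpr2 was at 0.45 (0.25 to 0.65) in donor and -0.33 (-0.66 to -0.01) in recipient cells. Of 5465 genes, 11 were at least 2-fold higher and 24 lower in both origins. With a minimum of 200 UMIs 6 were higher and 11 lower, and with 50 UMIs 20 were higher and 39 lower.

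In nonclassical monocytes, early inflammatory genes were lower with RvD1. Il1a, an alarmin cytokine, was at -2.29 (-2.82 to -1.79) and -2.28 (-2.92 to -1.68), the inflammasome sensor gene Nlrp3 at -1.34 and -1.82, Il1rn, the interleukin-1 receptor antagonist, at -1.12 and -1.93 and the transcription factor gene Nr4a3 at -1.51 and -1.39. Of 29 genes of the TNF and NF-kB early response, 11 were at least 1.5-fold lower in both origins and 0 higher, with medians of -0.57 (0.0) and -0.57 (0.0). Of 23 immediate early genes, which respond first to stimulation, 8 were lower, with medians of -0.52 (0.0) and -0.42 (0.05), and Egr1 was at -0.92 and -1.51. Genes of oxidative phosphorylation were higher, with medians of 0.51 (100) and 0.38 (100), and Ndufa6 of respiratory complex I was at 1.06 and 0.67. The ribosomal share of UMIs in this class also differed, at 9.21% with vehicle and 13.7% with RvD1 in donor cells. In recipient cells it was 9.70% and 13.1%. Ratios in this class had Spearman correlations with intron length of -0.29 in donor and -0.27 in recipient cells. Lgals1 (galectin-1) was at 1.65 and 1.08. Of 6254 genes, 21 were at least 2-fold higher and 113 lower in both origins. Clusters 10 and 15 formed this class, and without cluster 15, which carried S100a8 and S100a9, 7 genes were higher and 4 lower. The TNF medians were then -0.41 and -0.03, the recipient medians of immediate early genes -0.27 and of oxidative phosphorylation 0.07, Nlrp3 was at -0.09 and Il1rn at 0.29 in recipient cells, and Egr1 was at -0.05 and -0.54.

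In lymphocytes, single heat shock genes were lower with RvD1 in T and NK cells. In T cells Hsph1, a large heat shock protein, was at -1.18 (-1.45 to -0.91) in donor and -1.19 (-1.45 to -0.93) in recipient cells and Hsp90aa1 at -0.82 and -0.69; the heat shock medians were -0.28 (percentile 5.01) and -0.31 (0.09). In NK cells they were -0.31 (3.29) and -0.42 (0.01), with Hsp90aa1 at -0.66 and -0.55, and in B cells -0.03 (89.6) and -0.16 (20.6). Hist1h1e, a linker histone gene, was higher at 1.28 and 1.58 in T cells and at 1.62 and 1.25 in NK cells. In T cells it was at 2.30 and 0.95 with each library clustered alone. The chemokine gene Ccl3 was higher in NK cells at 1.40 (1.03 to 1.77) and 1.54 (0.96 to 2.16), and Ccl4 was at 0.52 and 0.50. Txnip, a thioredoxin inhibitor, was at 0.64 and 0.61 in T cells and at 1.14 and 0.60 in NK cells. Oxidative phosphorylation genes had medians of 0.39 (100) and 0.13 (100) in T cells and of 0.37 (100) and 0.15 (100) in B cells, with Ndufa13 of respiratory complex I at 0.72 and 0.33 in T cells. The recipient T cell median was 0.01 with each library clustered alone, and after subtraction of the intron-length trend the medians were 0.29 and 0.08 in T cells and 0.28 and 0.09 in B cells. The ribosomal share of UMIs also differed, at 23.4% with vehicle and 28.3% with RvD1 in donor T cells and at 20.04% and 26.8% in donor B cells. In recipient cells it differed less, at 34.0% and 35.5% in T cells and at 24.2% and 25.95% in B cells. Bcl2a1b, a survival gene, was at 1.70 and 1.10 in B cells. The numbers of genes at least 2-fold higher and lower in both origins were 14 and 23 of 8422 in T cells, 15 and 0 of 6182 in B cells and 13 and 4 of 6149 in NK cells. Gpr18, described as a receptor for resolvin D2, was at 0.01 and 0.19 in T cells, -0.15 and 0.03 in B cells and 0.18 and 0.25 in NK cells. The median of all genes was -0.12 in donor T cells and -0.28 in donor B cells.

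DCs were compared in donor cells only. The inducible chaperone gene Hspa1a was at -2.40 (-2.63 to -2.19), Gbp2 at -1.43 (-2.14 to -0.79) and Gpr18 at -1.10 (-1.77 to -0.47), and the interferon list had a median of -0.57 (percentile 0.0). Of 6842 genes, 54 were at least 2-fold higher and 193 lower with RvD1. A single cell held 36.3% of the Cxcl10 UMIs, so its ratio of -4.84 rests on few cells.

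The third question was how recipient cells that had entered the graft differed from donor cells of the same class, with vehicle and then with RvD1. Recipient neutrophils had lower inflammatory chemokine genes. Ccl3, which attracts monocytes, was at -1.43 (-1.48 to -1.37) with vehicle and -1.68 (-1.74 to -1.62) with RvD1, from 708 and 709 CPM in donor to 263 and 221 CPM in recipient neutrophils. The neutrophil attractant gene Cxcl1 was at -1.08 (-1.49 to -0.66) and -1.45 (-1.87 to -1.03). Of 9 chemokine genes 4 were at least 1.5-fold lower in both treatments and 0 higher, with medians of -0.97 (percentile 0.0) and -0.57 (0.02). The TNF list had medians of -0.34 (0.01) and -0.17 (0.34), with Tnf itself at -0.80 and -1.26 and the adhesion gene Icam1 at -0.67 and -0.57. Tgfb1 was at -0.96 and -1.07 and the integrin gene Itgb1 at -1.07 and -1.01. Wfdc17 was at -1.44 and -1.68. Higher in recipient cells were the kinase gene Bmx at 1.20 (0.94 to 1.47) and 1.17 (0.95 to 1.38), the peptide transporter gene Slc15a2 at 1.76 and 1.08, and Gpx4, which reduces lipid peroxides, at 1.08 and 0.85. Alox5, which makes leukotrienes, was at 0.81 and 0.34. Apoptosis and survival genes had medians of -0.32 (1.54) and -0.35 (0.05), and interferon-stimulated genes -0.36 (0.21) with vehicle and 0.06 (86.1) with RvD1.

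Of 6868 genes, 10 were at least 2-fold higher and 41 lower in recipient neutrophils in both treatments, with a Spearman correlation of 0.51 across genes, which are not independent replicates. With each library clustered alone, the vehicle values were -0.11 for the chemokine median, -0.14 for Ccl3, -0.15 for Tnf, -0.34 for Tgfb1 and 0.18 for Bmx. The median of all genes with vehicle was -0.15.

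In recipient T cells, the immediate early, glycolysis, cytotoxic and adhesion lists were lower, and interferon-stimulated genes higher, than in donor T cells. Il17a, which recruits neutrophils, was at -5.13 (-7.43 to -3.55) with vehicle and -4.84 (-5.51 to -4.24) with RvD1, and its level was 14.3 and 48.6 CPM in vehicle and RvD1 donor cells and 0.409 and 1.69 CPM in recipient cells. Zbtb16, a transcription factor of innate-like T cells, was at -4.35 and -4.10. Of 22 immediate early genes 9 were at least 1.5-fold lower in both treatments, with Atf3 at -3.35 (-3.91 to -2.84) and -4.45 (-5.02 to -3.93), Fosb at -3.09 and -3.01 and Nr4a1 at -1.69 and -1.85; the medians were -0.40 (percentile 0.07) and -0.67 (0.0). Of 25 glycolysis and hypoxia genes 7 were lower, with Hk2 (hexokinase) at -2.48 and -3.22 and Hilpda at -1.71 and -2.27, and medians of -0.51 (0.0) and -0.56 (0.02). Of 14 cytotoxic genes 6 were lower, with Ifng at -2.28 and -1.13 and medians of -1.32 (0.0) and -0.79 (0.0). Of 20 adhesion and migration genes 7 were lower, with Ccr2 at -2.26 and -2.28, Cd44 at -1.61 and -2.25 and the chemokine receptor gene Cxcr4 at -1.36 and -1.61.

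Interferon-stimulated genes in T cells had medians of 0.55 (100) and 0.90 (100), with 8 of 22 at least 1.5-fold higher in both treatments and 1 lower. Usp18, which restrains interferon signalling, was at 1.24 (0.81 to 1.69) and 1.32 (0.76 to 1.93), Ifit1 at 0.96 and 1.53 and Gbp5 at 0.75 and 1.80. Of 8567 genes, 8 were at least 2-fold higher and 385 lower in recipient T cells in both treatments. The median of all genes was -0.20 with vehicle and -0.15 with RvD1; with scaling to that median 28 genes were higher. Different clusters held most T cells, 5 and 8 in recipient cells and 5, 8, 14 and 16 (vehicle) or 5, 12 and 14 (RvD1) in donor cells. Cluster 14, led by Il23r, Cd163l1 and Trdc, held 19.7% and 32.3% of vehicle and RvD1 donor T cells and 1.27% and 2.865% of recipient T cells. Cluster 16, led by Cd8b1 and Gzmk, held 21.5% and 15.2% of donor and 3.69% and 5.95% of recipient T cells. The ratios, those of Il17a and the cytotoxic genes among them, can therefore reflect a different mix of T cells. With each library clustered alone, the RvD1 values were -2.83 for Il17a, -1.59 for Hk2 and -2.55 for the cytotoxic median, and without doublet removal Cd44 was at -0.91 and -0.99.

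**Figure D4:**
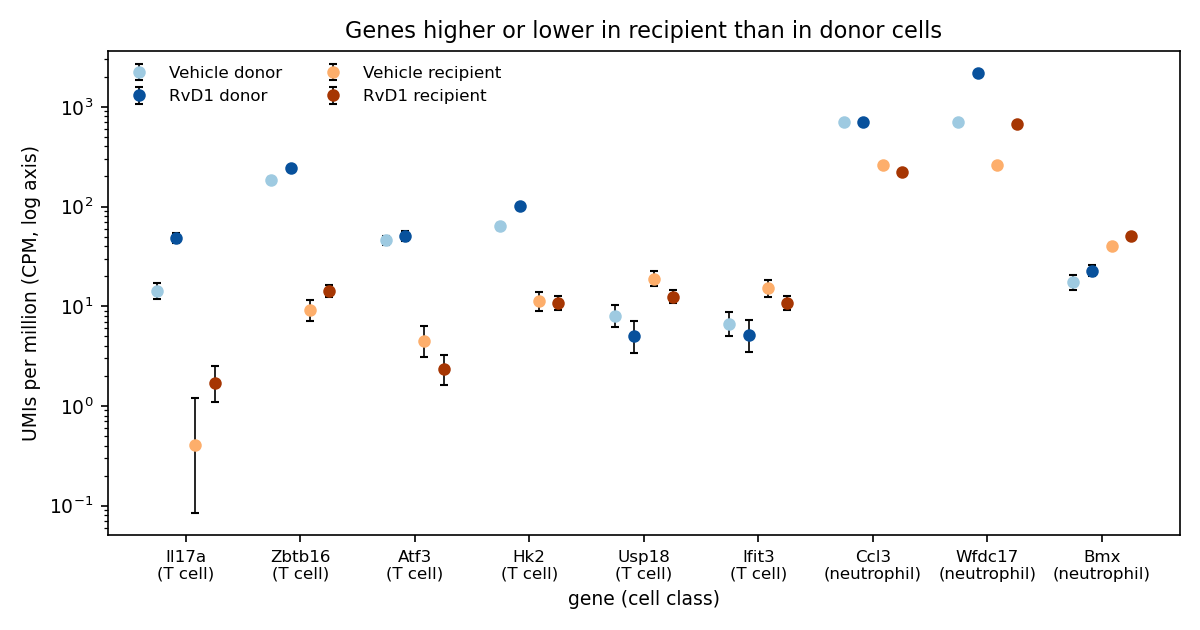
Level in CPM (log y axis) of genes in T cells and neutrophils (x axis) in the 4 libraries, with exact 95% Poisson intervals that cover counting error only. Il17a in T cells is at 14.3 and 48.6 CPM in donor and at 0.409 and 1.69 CPM in recipient cells.

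Recipient monocytes differed less from donor monocytes. In classical monocytes the interferon list was higher in recipient cells, with medians of 0.41 (percentile 100) and 0.56 (100), 3 of 22 members at least 1.5-fold higher in both treatments and 0 lower. Zbp1, a sensor of Z-form nucleic acid, was at 0.89 (0.69 to 1.07) and 0.94 (0.75 to 1.13), Slfn5 at 0.69 and 0.74 and Oasl2 at 0.52 and 1.13. Rtp4, also induced by interferon, was at 0.96 (0.73 to 1.19) and 1.22 (0.96 to 1.49). Lower were Pf4 (platelet factor 4) at -2.41 and -1.66, the matrix protease gene Mmp14 at -1.38 and -1.21 and C1qc, a complement gene of tissue macrophages, at -1.08 and -1.63. Of 7244 genes 1 was at least 2-fold higher and 7 lower. In nonclassical monocytes the interferon medians were 0.20 (99.99) and 0.17 (98.7), and the nuclear lamina gene Lmna was at -1.39 and -1.48; of 6664 genes 0 were higher and 5 lower. In B cells Slc15a2 was at 2.26 (1.81 to 2.75) and 2.92 (2.12 to 3.85), heat shock genes had medians of -0.23 (0.26) and -0.49 (0.0), and 1 gene was higher and 12 lower of 6640. In NK cells 0 genes were higher and 1 lower of 6287. Across genes, the vehicle and RvD1 ratios of these 4 classes had Spearman correlations from -0.09 to 0.10; genes are not independent replicates.

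Transcripts of other cells were measured as background. S100a8, an abundant neutrophil transcript at 29647 to 49359 CPM in neutrophils, was at 39.2, 152, 359 and 149 CPM in T cells of vehicle donor, RvD1 donor, vehicle recipient and RvD1 recipient libraries, at 28.996, 878, 258 and 101 CPM in B cells and at 36.7, 597, 466 and 125 CPM in NK cells. The surfactant gene Sftpc was at most 5.09 CPM in the classes compared and was not measured in the others. The haemoglobin gene Hbb-bs was at 142 CPM in RvD1 recipient T cells and at most 0.833 CPM in the other T cell libraries, and at 51.2 CPM in RvD1 recipient B cells and at most 1.90 CPM in the other B cell libraries.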

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

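Shares of neutrophils, nonclassical monocytes and NK cells lay in opposite directions in donor and recipient cells. Shares of a library depend on each other, so a shift in the neutrophil share alone moves those of the other classes the other way. The nonclassical monocyte and NK cell differences are therefore not independent of that shift. A neutrophil shift alone would move the other classes by a like factor, which does not give the donor values. There NK cells fell from 14.1% to 8.32% and nonclassical monocytes from 9.88% to 5.67%, while T cells moved from 15.1% to 13.6%. Classical monocytes rose from 9.84% to 14.5%, a difference of 0.727 points with each library clustered alone. Whether the recipient differences go beyond the shift was not tested. The neutrophil share was 12.1 percentage points higher with RvD1 in donor cells and differed by -16.0 points in recipient cells. It was 17.7 and -9.98 points with Leiden resolution 2, and 22.7 points in donor cells with each library clustered alone. The nonclassical monocyte share differed by -4.21 points in donor and 1.63 points in recipient cells, and the NK cell share by -5.77 and 1.43 points. What set these apart, among the classes compared in both origins, is that the 2 origins lay on opposite sides of 0 by more than counting error; the difference was not tested. T cell shares also lay in opposite directions, with overlapping intervals in donor cells. DC shares did so too (5.66% and 3.80% of donor, 0.275% and 0.613% of recipient cells), from 16 and 45 recipient cells.

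Neutrophil granule genes also lay in opposite directions in classical monocytes and T cells, and in the same direction in nonclassical monocytes (-0.16 and -2.16). In classical monocytes their median log2 ratio of RvD1 over vehicle was 1.27 in donor and -0.62 in recipient cells, and in T cells it was 1.04 and -1.23; the difference was not tested. In T cells only 4 members were measured in both origins. S100a8 in T cells followed the same order, at 39.2 and 152 CPM in vehicle and RvD1 donor cells and at 359 and 149 CPM in recipient cells. In B cells it was at 878 CPM in RvD1 donor and 258 CPM in vehicle recipient cells, so it did not follow the neutrophil share across libraries. Background RNA was not modelled.

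For the genes lower with RvD1 in neutrophils of both origins, none of the tests below was among the comparisons fixed before the data were examined. The correction for intron length and the share of genes without an abundant neighbour were chosen only after the result was seen. The test within clusters 1 and 3 could be chosen only once the clusters had been seen. The intron correction left 95.31% of these genes at least 2-fold lower. It subtracts only a shift shared by genes of like intron length, and that shift was small in neutrophils. Their ratios had Spearman correlations with intron length of -0.12 in donor and -0.14 in recipient cells. The correlation was negative in every class compared in both origins, down to -0.49 in donor B cells. The correction argues against such a shared shift as the cause, and unspliced RNA of single genes stays open. Within clusters 1 and 3, 95 of the 257 genes had enough UMIs in donor and 174 in recipient cells. Their medians there were -0.76 (-0.7552) and -0.77, against -1.38 and -1.49 for the same genes in all neutrophils, so they stayed lower within these clusters. The clusters were drawn from the same expression values, and cluster 0 was led by genes of this set, among them Cc2d2b, Fnip2 and Pnpla7. A different mix of cells and a change of state in the same cells therefore cannot be told apart by cluster. A same-strand gene within 20000 bp upstream with at least 4-fold its level was found for 14.45% of the genes (37 of 256) against 3.91% in matched sets, and 85.55% had none, so transcripts running on from a neighbour may explain some genes and not the set. A difference in library or software version cannot be told apart, since each treatment has its own Cell Ranger version. Those of the 257 genes with enough UMIs had medians of -0.32 (141 genes) and -0.23 (140) in donor and recipient T cells. In B cells they were -0.40 (-0.4038, 106 genes) and -0.23 (132), where all genes in donor cells had -0.28, and in NK cells -0.25 (127) and -0.17 (97). In neutrophils all 257 genes had -1.48 and -1.60, so the sets compared are not the same. An effect of RvD1 on neutrophil state stays open beside these explanations.

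For the interferon-stimulated genes lower with RvD1, the comparison with B and NK cells and the intron correction were tests chosen only after the result was seen. The test without cluster 13 could be chosen only once the clusters had been seen. The lowest percentile of the list in B and NK cells was 28.17, with 8 and 11 members measured there in both origins against 25 in neutrophils. The 13 members described in donor NK and T cells had medians of -0.01 and -0.80, and the 8 in donor B and T cells -0.14 and -0.76, which argues against a difference that acts on these members in every class and leaves the others open. The intron correction kept at least 94.13% of the medians in neutrophils, classical monocytes and T cells. This argues against a shift shared by genes of like intron length, and unspliced RNA of single members stays open. Without cluster 13, led by interferon-stimulated genes, the neutrophil median kept 34.31% of its value in donor and 64.2% in recipient cells, so fewer responding cells and a lower level per cell cannot be told apart. Less interferon exposure with RvD1 could give this pattern in several classes, as could a difference between the pooled lungs or animals of each library, which was not tested.

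For the genes lower with RvD1 in nonclassical monocytes, leaving out cluster 15 was a test chosen only after the result was seen. Of 113 genes, 8.85% (10 genes) stayed at least 2-fold lower without it when no minimum of UMIs was set, and with the minimum of 100 UMIs 4 genes in all were lower. Cells of cluster 15 with at least 10 UMIs of S100a8 and S100a9 made up 99.1%, against 2.33% in cluster 10, and 68.1% of the 113 genes were at least 4-fold higher in neutrophils than in cluster 10. That 68.1% is given without the share over all described genes, so by itself it shows no enrichment. Monocytes joined to neutrophils or carrying their RNA are a candidate explanation, because the median UMI count was 19310 in cluster 15 and 10805 in cluster 10 of vehicle donor cells. An activated monocyte state that makes these transcripts itself also stays open.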

How the results depend on the processing

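The 675 results were recomputed under 15 settings, 7854 comparisons in all, of which 7125 stayed within their spread, 688 moved and 41 turned direction. Of 865 values of list medians 205 moved and 13 turned, of 6789 values of named genes 445 moved and 28 turned, of 124 gene counts 28 moved, and of 72 share differences 6 moved. A minimum of UMIs only selects genes and leaves the ratio of a kept gene unchanged. The 579 values of named genes at 50 UMIs and the 410 at 200 UMIs therefore stayed by construction. Thinning lowers the genes per cell by design, and those 4 medians are among the values that moved. The spread was not the same measure for every kind of result, so the totals do not measure robustness. For every value below, the cause was not tested. Leiden resolution 0.5 moved 2 named genes, a minimum of 500 genes moved 6 list medians and 5 named genes, and neither turned a direction or moved a gene count or share difference. No paired analysis was possible because each group is 1 library and the labels pair none of them, and no result comes from a test. The 2 origins hold different cells and were not used as pairs. When each library was clustered alone, 2 of the 10 gene counts had no value, and several genes of nonclassical monocytes, among them Il1a, had none without cluster 15.

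With Leiden resolution 2, the TNF and NF-kB list in neutrophils, RvD1 over vehicle, was at 0.12 in donor and 0.0232 in recipient cells in place of -0.25 and -0.13, and Il1a was at 0.35 and 0.15 in place of -0.74 and -0.53. Tmem176b in donor nonclassical monocytes was at -0.0612 in place of 1.13. Genes higher in recipient neutrophils numbered 6. The interferon list was at -1.02 in donor neutrophils, -0.43 in recipient classical monocytes and 0.44 for recipient over donor classical monocytes with RvD1. Neutrophil shares differed by 17.7 points in donor and -9.98 in recipient cells. Oxidative phosphorylation in recipient over donor neutrophils with vehicle was at -0.004 in place of 0.0462.

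With a minimum of 200 UMIs, chemokines in recipient over donor nonclassical monocytes with vehicle were at 0.0604 in place of -0.39. With RvD1, 6 genes were higher and 11 lower in classical monocytes, 15 higher in neutrophils and 71 lower in nonclassical monocytes, and 24 were lower in recipient neutrophils. The interferon list was at -0.38 in recipient T cells and 0.50 in recipient over donor classical monocytes with vehicle. With a minimum of 50 UMIs, chemokines in recipient over donor neutrophils with RvD1 were at -0.75, and swarming genes in T cells with vehicle at 0.11 in place of -0.65. Then 17 genes were higher in recipient T cells and 70 lower in recipient neutrophils, 20 were higher and 39 lower with RvD1 in classical monocytes and 48 higher in neutrophils, and the interferon list in donor neutrophils was at -0.91.

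With at most 5% mitochondrial UMIs, Fn1 in recipient over donor nonclassical monocytes with vehicle was at 0.34 in place of -0.86. Lyz2 in recipient B cells was at -0.51 in place of 0.999. S100a6 in recipient over donor B cells with vehicle was at 0.56 in place of -1.17. Tmem176b in donor nonclassical monocytes was at -0.19 in place of 1.13. The classical monocyte share differed by 1.11 points in recipient cells, and 12 genes were higher with RvD1 in nonclassical monocytes. The interferon list was at -0.93 in donor T cells, -0.51 in recipient classical monocytes and 0.48 in recipient over donor classical monocytes with RvD1.

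With each library clustered alone, Hist1h1b in recipient NK cells was at -0.10 in place of 1.49 and Plxdc2 in donor T cells at -0.22 in place of 1.17. Il1a in donor neutrophils was at 0.65 in place of -0.74 and the TNF list there at 0.0681 in place of -0.25. The inflammasome list in recipient T cells was at -0.29 in place of 0.26. Oxidative phosphorylation in recipient over donor neutrophils with vehicle was at -0.14 in place of 0.0462. Shares differed by 5.69 points for T cells in recipient cells, 0.727 for classical monocytes in donor cells and 22.7 for neutrophils in donor cells. With RvD1, 15 genes were higher and 159 lower in neutrophils. Chemokines in recipient over donor neutrophils with vehicle were at -0.11, and the interferon list was at -0.60 in donor classical monocytes, -0.0332 in donor neutrophils and -0.20 in recipient T cells.

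With equal weight for every cell, the TNF list in recipient nonclassical monocytes was at -0.36, 18 genes were higher in recipient T cells, and with RvD1 46 were higher in neutrophils and 11 in nonclassical monocytes. The interferon list was at -0.94 in donor neutrophils, 0.45 in recipient over donor classical monocytes with RvD1 and 0.63 in T cells with vehicle. With every cell thinned to 500 UMIs, the median genes per cell were 351 in vehicle donor, 332 in RvD1 donor, 319 in vehicle recipient and 318 in RvD1 recipient cells.

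Without doublet removal, Fn1 in recipient over donor nonclassical monocytes with vehicle was at 1.21 in place of -0.86. In recipient T cells H2-Aa was at 0.11 in place of -2.11 and H2-Eb1 at 0.013 in place of -1.999. In B cells, RvD1 over vehicle, Jchain was at -8.79 in place of 3.82 in donor cells. Lyz2 was at -0.0114 in place of 0.999 in recipient B cells. Recipient over donor B cells with RvD1, Jchain was at 5.53, Mt1 at 0.19, S100a6 at 0.0325 and Xbp1 at 0.22. Their main values were -3.79, -3.18, -1.23 and -1.71 in that order. With vehicle Lyz2 was at 0.20 in place of -1.71 and S100a6 at 0.30 in place of -1.17. Swarming genes in recipient over donor T cells were at 0.21 with vehicle and 0.32 with RvD1, in place of -0.65 and -0.64. Chemokines in neutrophils with vehicle were at -0.83, 17 genes were higher in recipient T cells, and the interferon list was at 0.78 in T cells with RvD1 and 0.50 in classical monocytes with vehicle.

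With scaling by the median ratio, Fpr2 in recipient neutrophils was at -0.0398, chemokines in recipient over donor neutrophils with vehicle at -0.82, and 28 genes were higher in recipient T cells and 16 in recipient neutrophils. The interferon list, RvD1 over vehicle, was at -0.70 in donor T cells and -0.40 in recipient neutrophils, and recipient over donor at 1.05 (RvD1) and 0.75 (vehicle) in T cells and 0.64 in classical monocytes with RvD1. With a total without mitochondrial, ribosomal and haemoglobin genes, 34 genes were higher in recipient T cells, and the interferon list was at -0.71 in donor T cells and, recipient over donor, at 1.07 with RvD1 and 0.78 with vehicle.

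The next settings were chosen after seeing the data. After subtraction of the intron-length trend, Fpr2 in recipient neutrophils was at -0.10, the TNF list in recipient nonclassical monocytes at -0.67, 29 genes were higher in recipient T cells and 11 higher with RvD1 in nonclassical monocytes. The interferon list was at -0.42 in recipient neutrophils and, recipient over donor, at 1.06 (RvD1) and 0.70 (vehicle) in T cells and 0.48 in classical monocytes with vehicle. Without cluster 0, the TNF list in neutrophils was at 0.21 in donor and 0.19 in recipient cells and Il1a at 0.40 and 0.28. Ltb4r1 in donor neutrophils was at -0.0634 in place of 0.41. Then 15 genes were higher and 92 lower with RvD1, 5 were higher in recipient neutrophils, and the interferon list was at -1.50 in donor and -0.83 in recipient neutrophils. Recipient over donor with vehicle, chemokines were at -1.14 and oxidative phosphorylation at -0.17. Without cluster 15, the TNF list in nonclassical monocytes was at -0.41 in donor and -0.0264 in recipient cells, and 7 genes were higher and 4 lower with RvD1. In recipient nonclassical monocytes Fpr2 was then at 0.57 in place of -0.75 and Il1rn at 0.29 in place of -1.93.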

Other observations

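A list of lysosomal and vacuolar ATPase genes, with some autophagy and nutrient-sensing genes, had lower medians with RvD1 in neutrophils and both monocyte classes. The medians in neutrophils and nonclassical monocytes depended on which clusters were kept. In donor and recipient neutrophils the nutrient-sensing gene Flcn was at -1.57 and -1.84 and the autophagy gene Uvrag at -1.45 and -1.20. Vacuolar ATPase genes were mixed, with Atp6v1a at -0.90 and -0.68 and Atp6v1g1 at 0.68 and 0.16. This list was written after some of its members had been seen, and those 6 members were left out. In neutrophils the medians of 36 measured members were -0.43 in donor and -0.47 in recipient cells, with 15 and 17 members at least 1.5-fold lower and 1 higher in each. In classical monocytes the medians were -0.25 (percentile 0.32) and -0.28 (0.08), and in nonclassical monocytes -0.31 (0.68) and -0.17 (2.4). Without cluster 0, which held most vehicle neutrophils, the neutrophil medians were -0.22 (percentile 3.32) in donor and -0.16 (0.41) in recipient cells. Without cluster 15 those of nonclassical monocytes were -0.28 (1.8) and 0.12 (99.4), so the recipient value turned direction. The percentiles were 25.04 and 6.71 in T cells, 85.4 and 35.05 in B cells and 91.4 and 76.4 in NK cells. Recipient neutrophils had lower levels than donor neutrophils, with medians of -0.38 with vehicle and -0.35 with RvD1.

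Lower expression of a lysosomal and vacuolar ATPase gene programme in phagocytes given RvD1 is offered as a hypothesis. Its test, made on the same data that raised it, put the list at percentile 0.01 in donor and 0.0 in recipient neutrophils among random lists. A different mix of neutrophil clusters could give much of it, as could less phagocytic cargo at 2 h or the difference in software version between treatments. Counts of acidified phagosomes in fresh grafts, with each lung kept apart, would test only its part on acidification.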
